A study of Ovis aries with 8 samples.

How the data were processed

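Total RNA was measured by RNA sequencing in 8 samples of fetal sheep cerebral cortex, all at a gestational age of 90 days. The cortical plate is the layer of the developing cortex in which newly made neurons settle. From each of 4 fetuses, carried as 2 fetuses by each of 2 ewes, one sample was taken from the cortical plate of a gyrus (an outward fold) and one from that of a sulcus (an inward groove). The animals were Border Leicester/Merino sheep and received no treatment. Per the labels' protocols, RNA was extracted with a micro-scale kit and amplified by single primer isothermal amplification (SPIA), which makes enough cDNA for a library from small amounts of RNA, and libraries were finished with an ultra-low-input kit. Amplification copies the molecules present at the start, so reads are not independent molecules. The counting error given below is worked out from reads alone and leaves out noise from amplification. Intervals of fold changes came from a fit that also estimates how the gyrus to sulcus difference varies between fetuses.

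The authors deposited one table of raw counts per gene with 27054 sheep Ensembl gene identifiers and 8 columns, with no row of unassigned reads. The submitters' processing notes name STAR 2.4.2a (an aligner), featureCounts (a read counter) and edgeR 3.4.2, with no role or order. The genome build, the annotation release and whether counting used strand are not given in the sources used here. Reads of overlapping or near-identical genes can therefore be split or lost in ways that these counts do not show. Total counts per library lay between 14788987 and 23927215. Of the columns, 6 carry the sample descriptions exactly. The other 2 carry one digit more than the descriptions of the gyrus and sulcus of ewe 2 fetus 1. They were assigned to that fetus because the only other descriptions that differ by one digit have exactly matching columns of their own. Region and pairing of these 2 libraries are plain from the column names, and only the ewe rests on this reading.

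The table does not pair identifiers with gene names or positions. The gene reference given (35057 genes of another annotation) matched 0 of the identifiers. The 29 gene lists fixed before the data were examined (cell types, cortical layers, signalling, matrix, stress, and genes named in connection with the study) could therefore not be tested. Neither could GC content nor gene length. No gene is named here by symbol.

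The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3, robust fit) on the deposited counts, with TMM scaling and the default expression filter (minimum count 10), which kept 13221 genes. Fetus was a block and the tested effect was gyrus minus sulcus. The series design states that both regions came from each specimen, so the block was part of the design fixed before the data were examined. The pairing was also seen in the data: deviations from the region means correlated at 0.21, 0.26, 0.36 and 0.43 between the gyrus and sulcus libraries of the same fetus, and among the libraries of the other region every library correlated best with its own partner. Libraries of the same region were not compared in this way. The threshold was a Benjamini-Hochberg adjusted p below 0.05. Intervals of 95% for log2 fold changes came from the same fit and were not adjusted for the number of genes. A region by ewe interaction was tested in the same model. The rule for genes to be named asked for a symbol, and this part could not be met. The conditions of a mean raw count of at least 20 and the same direction in 4 of 4 fetuses were kept. The rule also set more genes per direction, and more for the interaction, than are given here. Only the 2 genes per direction with the smallest unadjusted p are given, by identifier. Any other gene given by identifier was chosen after its values were seen. Log2 differences within a fetus used log2 CPM (counts scaled by the TMM-adjusted library size, as edgeR computes them) with a prior count of 2.

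The procedure was tested on simulated data drawn with the real means, library sizes and dispersions of the gyrus against sulcus comparison, with 200 genes changed. At a 2-fold change it recovered 57% of the changed genes, and 98.8% of the 81 changed genes at 32 CPM or more, in 12888 tested genes. At 1.5-fold the shares were 18.5% and 46.4% (of 69 genes, in 12881 tested), and at 4-fold 88% and 100% (of 85 genes, in 12894 tested). Of the calls, 3 of 40 were false at 1.5-fold, 11 of 125 at 2-fold and 11 of 187 at 4-fold. With no gene changed it called 0 of 12873. Simulated genes varied independently of each other, and each change had the same fold in all 4 fetuses. The shares recovered may therefore be too high for changes that differ between fetuses or ewes.

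Alternatives were the fit without the block, the ewe as block, DESeq2 1.42.0, limma-voom (limma 3.58.1) with fetus as a fixed or a random effect, edgeR's likelihood ratio test, DESeq2 size factors, upper quartile scaling and library totals in place of TMM, no low count filter (20941 genes), a stricter filter (at least 5 CPM in at least 4 libraries, 8774 genes), an adjusted p below 0.1, each fetus left out in turn, and each ewe alone. Counts thinned at random to the smallest total were added after the data were seen. All pairs of libraries were compared by chi-square. For every pair the chi-square per degree of freedom, which compares variances, was at least 23.0 times that of counting error alone, so none was a repeat deposit. Between libraries of the same region the lowest value was 40.3.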

Results

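The data set compared the cortical plate below gyri with that below sulci in fetal sheep at 90 days of gestation, during the folding of the cortex. It held 4 gyral and 4 sulcal libraries, one of each from 4 fetuses. In ewe 1, the total counts were 21298779 (gyrus) and 19203813 (sulcus) for fetus 1, and 23927215 and 20277649 for fetus 2. In ewe 2 they were 17768173 and 14788987 for fetus 1, and 22054753 and 19303647 for fetus 2. The means were 21262230 ± 2578114 in gyri and 18393524 ± 2451361 in sulci (SD, n = 4 each). The gyral library was the deeper one in 4 of 4 fetuses (exact two-sided sign-flip permutation test, p = 0.125, the smallest p that 4 pairs allow). At an equal depth of 14788987 counts, 16699 ± 701 genes were detected in gyri and 16301 ± 685 in sulci (SD, n = 4 each), with more in the gyrus of 3 of 4 fetuses (exact sign-flip permutation test, p = 0.25). The most abundant gene took 3.46% to 4.45% of the counts in the 6 libraries of the first 3 fetuses. In ewe 2 fetus 2 it took 1.17% in the gyrus and 1.53% in the sulcus. The 10 most abundant genes took 13.3% to 16.5% of the counts in those 6 libraries, and 7.58% and 8.34% in the gyrus and sulcus of ewe 2 fetus 2.

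The first question was how much of the variation in expression followed the region. Fetuses differed more than regions did. Of the sum of squares of log2 CPM over 13221 genes, fetus accounted for 58.5% with 3 degrees of freedom, and region for 10.6% with 1 degree of freedom. The rest, 30.9%, had 3 degrees of freedom, so the mean square of region was 1.03 times that of the rest. Exchanging gyrus and sulcus within fetuses gave a region share at least as large in 3 of 8 arrangements, the real one included. The difference between ewes held 24.5% of the sum of squares, as part of the fetus share. Across genes, log2 CPM of gyrus and sulcus of the same fetus correlated at 0.957 to 0.985 (median 0.961, 4 pairs). Libraries of the same region from different fetuses correlated at 0.930 to 0.963 (median 0.954, 12 pairs), and libraries of different region and fetus at 0.935 to 0.966 (median 0.953, 12 pairs). The gyrus of ewe 1 fetus 2 correlated at 0.966 with the sulcus of ewe 2 fetus 2 and at 0.963 with its own sulcus, so the ranges overlap. Genes are not independent replicates in these correlations.

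Single genes were then compared between gyrus and sulcus. No gene passed the threshold: 0 of 13221 genes had an adjusted p below 0.05 in edgeR's quasi-likelihood test, and the lowest adjusted p was 0.99. At an unadjusted p below 0.05, 512 genes were counted, 240 with higher and 272 with lower values in the gyrus. With no difference at all, 661 would be counted on average. Genes are not independent, so such counts can lie far from their average without a difference. Other arrangements of the region labels within fetuses gave up to 880. DESeq2 and limma-voom, both with the fetus block, also called 0 genes, with 619 and 559 genes at an unadjusted p below 0.05. The lowest adjusted p was 0.0762 with DESeq2 and 0.993 with limma-voom. The gyrus to sulcus difference had the same sign in all 4 fetuses for 12.6% of genes, against 12.5% by chance. Within the fetuses of ewe 1 alone the test called 1 gene, with 614 at an unadjusted p below 0.05, where 667 would be counted by chance. Within those of ewe 2 alone it called 0, with 958 against 674.

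**Figure D1:**
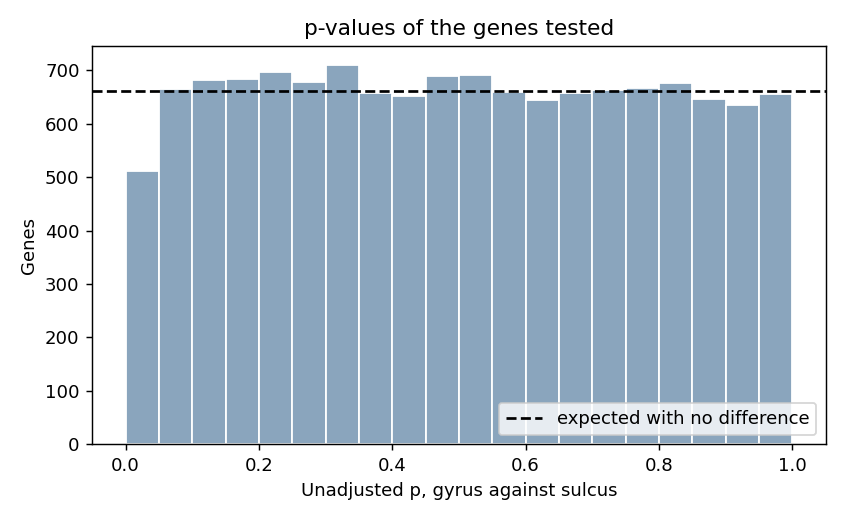
Histogram of unadjusted p-values (x axis, bins of 0.05) of the 13221 genes tested between gyrus and sulcus, with the number of genes on the y axis. The dashed line is the 661 genes per bin expected with no difference; the first bin holds 512 genes.

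How large a difference the data leave room for depended on abundance. For 8740 of the 13221 genes (66.1%), the 95% interval of the gyrus to sulcus fold change excluded a 2-fold difference in either direction. Among the 4235 genes at 32 CPM or more, it excluded 2-fold for 4205 (99.3%) and 1.5-fold for 3791 (89.5%). The median standard error of the log2 fold change was 0.24 over all genes and 0.13 at 32 CPM or more. Of those abundant genes, 1 had an estimated fold change above 2. The fit counts the gyrus to sulcus difference of each fetus as independent, although the fetuses came from 2 ewes. At 30 CPM or more, these differences correlated at 0.26 between the fetuses of ewe 2 and at -0.0097 between those of ewe 1. Fetuses of different ewes gave -0.139 to -0.013. The intervals may therefore be too narrow for fetuses of other ewes.

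Under the parts of the naming rule that were kept, 2 genes in each direction were taken, fewer than the rule set. None of the 4 passed the correction for the number of genes tested. ENSOARG00000009322 had 189 ± 32.1 CPM in gyri and 126 ± 11.6 CPM in sulci (SD, n = 4 each), a log2 fold change of 0.57 ± 0.10 (SE). It was higher in the gyrus of 4 of 4 fetuses, by 1.34 to 1.62 times (edgeR quasi-likelihood test, adjusted p = 0.99). ENSOARG00000015199 had 52.4 ± 5.81 CPM in gyri and 33.3 ± 2.76 CPM in sulci, a log2 fold change of 0.65 ± 0.15 (SE). The ratio was 1.22 to 1.88 across the 4 fetuses (edgeR, adjusted p = 0.99). In the other direction, ENSOARG00000000135 had 59.4 ± 14.0 CPM in gyri and 87.8 ± 22.3 CPM in sulci, a log2 fold change of -0.56 ± 0.12 (SE; edgeR, adjusted p = 0.99). The scarce gene ENSOARG00000009537 had 0.415 ± 0.292 CPM in gyri and 2.13 ± 1.22 CPM in sulci, with raw counts between 1 and 71 per library. Its log2 fold change was -2.51 ± 0.63 (SE, edgeR, adjusted p = 0.99). With the prior count of 2, the ratio of sulcus to gyrus ran from 2.08 to 8.14 across the 4 fetuses. The 8.14 was in ewe 1 fetus 2, with raw counts of 20 in sulcus and 1 in gyrus, where the prior count lowers the ratio strongly. The log2 fold change of this gene was -3.56 in the fetuses of ewe 1 alone and -1.68 in those of ewe 2 alone. Both ENSOARG00000000135 and ENSOARG00000009537 were lower in the gyrus of 4 of 4 fetuses. All 4 genes were picked for a small p, a choice that favours overstated fold changes. For none of the 4 did the difference between the ewes in the gyrus to sulcus change pass the test (edgeR interaction test, adjusted p of 0.816 to 0.987). A choice of genes with one direction in 4 of 4 fetuses and a small p favours little variation between fetuses. This outcome was therefore likely beforehand and does not show that the ewes agree.

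**Figure D2:**
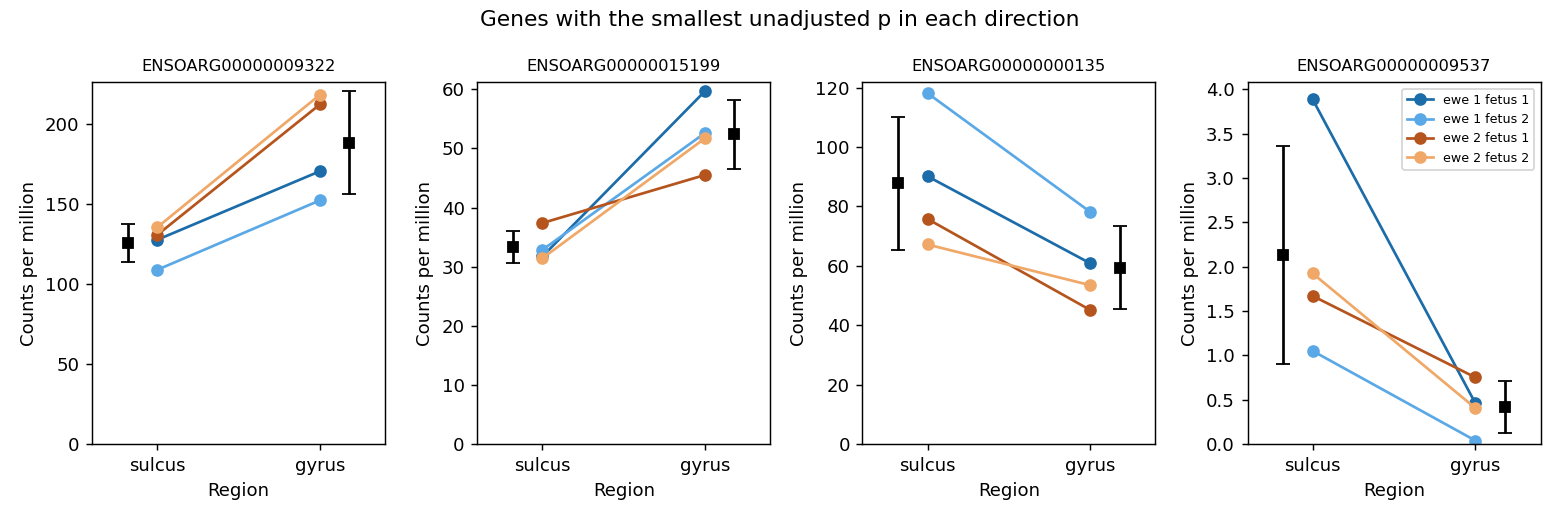
CPM (y axis, linear, from 0) of the 2 genes in each direction with the smallest unadjusted p among those with a mean raw count of at least 20 and one direction in 4 of 4 fetuses, in sulcus and gyrus (x axis); points joined by a line are the 2 libraries of one fetus, and black squares with bars are the mean ± SD of 4 libraries. All 4 lines rise from sulcus to gyrus for ENSOARG00000009322 (126 to 189 CPM on average) and ENSOARG00000015199 (33.3 to 52.4 CPM) and descend for the other 2 genes, whose means go from 87.8 to 59.4 and from 2.13 to 0.415 CPM; each has an adjusted p of 0.99.

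The spread between the gyral and the sulcal library of a fetus was then set against counting error. Among the 2237 genes at 1 to 3 CPM, the robust SD of the log2 ratio was 1.12 in ewe 1 fetus 1, 1.09 in ewe 1 fetus 2 and 1.13 in ewe 2 fetus 1. In ewe 2 fetus 2 it was 0.588. Counting error alone gives 0.369, 0.329, 0.373 and 0.315, so the variance was 9.18, 10.9, 9.20 and 3.49 times that of counting. Among the 526 genes at 300 to 1000 CPM the spread was 0.134, 0.194, 0.273 and 0.158 in the same order. The variance was above that of counting error in each abundance class of each fetus.

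**Figure D3:**
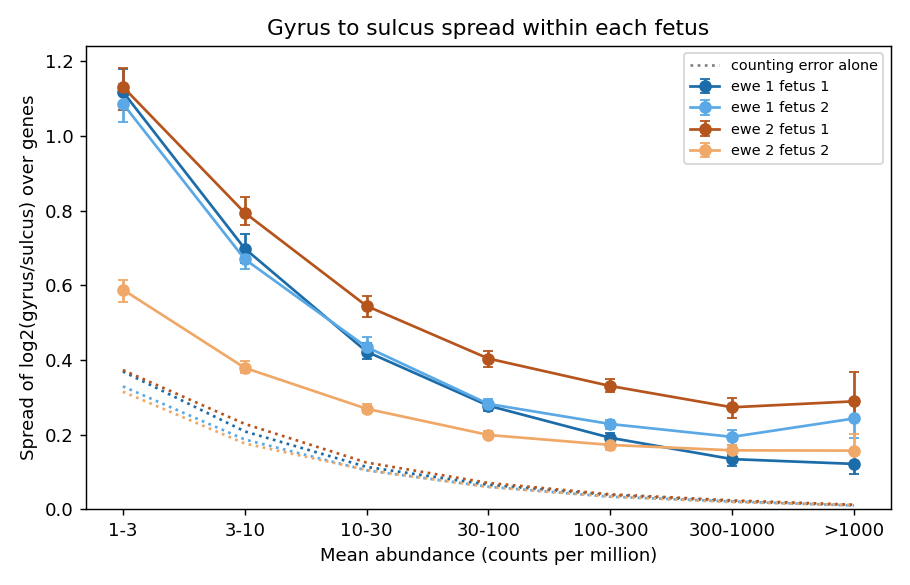
Robust SD over genes of log2(gyrus/sulcus) within each of the 4 fetuses (y axis) by mean abundance class in CPM (x axis); bars are 95% resampling intervals over genes and dotted lines the SD from counting error alone. At 1 to 3 CPM ewe 2 fetus 2 lies at 0.588 and the others at 1.09 to 1.13; at 300 to 1000 CPM ewe 2 fetus 1 is highest, at 0.273.

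The labels give 2 ewes, so the gyrus to sulcus change was compared between them. It differed for 1 of 13221 genes, and 825 genes had an unadjusted p below 0.05 where 661 would be counted by chance. Neither count was stable. Without the block 0 genes were called and 387 had an unadjusted p below 0.05. With a fetus left out, 8 (without ewe 1 fetus 1), 15 (ewe 1 fetus 2), 19 (ewe 2 fetus 1) or 23 genes (ewe 2 fetus 2) were called, and 1247, 1037, 371 or 1314 had an unadjusted p below 0.05. The gene, ENSOARG00000014361, is given because it was the only one called with all 4 fetuses and the block. It was lower in the gyrus of both fetuses of ewe 1, with log2 differences of -0.81 and -1.14. It was higher in the gyrus of both fetuses of ewe 2, with 0.96 and 1.45. The difference between ewes was 2.19 ± 0.27 on the log2 scale (SE; edgeR interaction test with the fetus block, adjusted p = 0.0257). Without the block the same difference was 2.21 with an adjusted p of 0.999, so the call rests on the pairing. Over all 4 fetuses together its gyrus to sulcus log2 fold change was 0.11 (edgeR, adjusted p = 0.995). Each ewe is represented by 2 fetuses only.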

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

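The tests of explanations in this part were chosen after the results were seen.

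Of 31 sets of 4 values examined (depth, detected genes, the share of abundant genes, the genes given by identifier and the spread within fetuses), 1 held a value far from the other 3, where chance would give 1.55. It was the spread between gyrus and sulcus at 1 to 3 CPM, 0.588 in ewe 2 fetus 2 against 1.09 to 1.13 in the others. The tables argue against depth as the explanation: with every library thinned to 14788987 counts, the smallest of the other spreads was still 1.78 times that of ewe 2 fetus 2. A candidate explanation is that fewer RNA molecules entered the amplification in the other samples, which adds noise to scarce genes and little to abundant ones. Ewe 1 fetus 1 went with this, with 1.90 times the spread of ewe 2 fetus 2 at 1 to 3 CPM. Its ratio was 0.851 (interval 0.682 to 1.04) at 300 to 1000 CPM. In the 109 genes above 1000 CPM it was 0.774 (interval 0.469 to 1.26). Ewe 1 fetus 2 had 1.85 times the spread at 1 to 3 CPM and 1.23 times at 300 to 1000 CPM. Its ratio above 1000 CPM was 1.55 (interval 0.955 to 2.43), which leaves the explanation open. For ewe 2 fetus 1 the tables argue against it as the whole cause, since its spread was still 1.73 times as large at 300 to 1000 CPM (1.43 at the low end of its interval); a larger biological difference between its regions and a difference in tissue quality stay open and untested.

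The gyrus to sulcus change of ENSOARG00000014361 differed between the ewes by 2.1877 on the log2 scale, in a test of the difference itself.

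The gyrus to sulcus differences of the 2 fetuses of ewe 2 were also correlated. Over the 7085 genes at 10 CPM or more, the correlation was 0.21 (resampling interval over genes 0.17 to 0.24). The 2 fetuses of ewe 1 gave -0.015, and fetuses of different ewes -0.106 to 0.037. The interval covers the choice of genes only, and genes are not independent replicates. Each ewe has 1 pair of fetuses, so how much the correlation varies between pairs within an ewe is not known. The value for ewe 2 depended on the abundance limit, with 0.12 at 1 CPM or more (12108 genes), 0.26 at 30 and 0.31 at 100 CPM or more, where fetuses of different ewes correlated at -0.219 to -0.098. Depth does not account for it, since the correlation was 0.2035 at equal depth, nor does a bias that follows abundance, with 0.2062 after such a trend was removed. The source of the correlation in ewe 2 cannot be told apart. A litter, the cortical site or manner of dissection and a shared processing day may each produce it, and the labels separate none of them. The 3 ways to pair the 4 fetuses are too few for a share under 0.05; the real pairing gave 825 genes at an unadjusted p below 0.05 in the interaction, as the only 1 of the 3 with that many, and the highest other gave 451.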

How the results depend on the processing

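The count of 0 genes between gyrus and sulcus was also 0 in the main fit under an adjusted p below 0.1. At the 0.05 limit it was 0 without the replicate block (205 genes at an unadjusted p below 0.05 against 512 with it). It was 0 with the ewe as block (269 at an unadjusted p below 0.05), with DESeq2 and with limma-voom of either kind. The likelihood ratio test (lowest adjusted p 0.107), the other scalings, the stricter filter and equal depth also gave 0. In DESeq2 the lowest adjusted p, 0.0762, was that of ENSOARG00000009322, which the 0.1 limit would call there. The count became 5 without a low count filter, with 909 genes at an unadjusted p below 0.05. None of the 5 was a gene that the filter removes. All 5 were also tested in the main fit, with nearly the same log2 fold changes (edgeR quasi-likelihood test, adjusted p 0.99 each). These 5 were 2 genes with the same direction in all 4 fetuses, ENSOARG00000010861 (log2 fold change -1.02, adjusted p 5.14e-04) and ENSOARG00000009322 (adjusted p 0.0226), and 3 with mixed directions, ENSOARG00000016718 (adjusted p 2.02e-42), ENSOARG00000008435 and ENSOARG00000000078 (adjusted p 0.0226 each); the cause was not tested. It was 0 to 1 with each fetus left out, and 1 in the fetuses of ewe 1 only. The 1 gene, called without ewe 2 fetus 2 and in ewe 1 alone, was again ENSOARG00000000078. Its log2 differences were positive in the other 3 fetuses (up to 1.61) and -1.35 in ewe 2 fetus 2 (with the filter, adjusted p 0.0225 without that fetus and 0.99 with it). The fetuses of ewe 2 only gave 958 genes at an unadjusted p below 0.05. The interaction between region and ewe called 1 gene with limma-voom, DESeq2 size factors and equal depth, and 0 without the replicate block. With a fetus left out, an alternative added after the data were seen, it called 8 (ewe 1 fetus 1), 15 (ewe 1 fetus 2), 19 (ewe 2 fetus 1) or 23 genes (ewe 2 fetus 2). Those fits have 1 pair in one ewe, which is assumed to vary like the other ewe's. The fit without the block was run for the gyrus to sulcus comparison and the interaction with all 4 fetuses, and between them the block changed only the call of the interaction. The 4 genes given by identifier in the main comparison kept their direction in every alternative that tested them (17 or 18 each). They had been picked for one direction in 4 of 4 fetuses, and the alternatives used the same fetuses. A kept direction was therefore nearly certain beforehand and adds no support. The number of genes whose interval excluded a 2-fold difference stayed within 1.5 times of 8740. The gene list tests and the GC and length correction were not run, because identifiers were not paired with names or sequences. At equal depth 502 genes had an unadjusted p below 0.05, so the depth of these libraries moved that count little.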

Other observations

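The tests in this part were chosen after the results were seen.

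A small set of genes differed strongly between fetuses. Of 14 possible sets of fetuses, genes were sought with at least 5 CPM in both libraries of the set and at least 20 times the level of every other library. The set of fetus 1 of ewe 1 with fetus 1 of ewe 2 held 5 such genes, and the other sets together 4 (3 in ewe 1 fetus 2 alone and 1 in ewe 2 fetus 1 alone). The raw counts of the 5 were 202 to 14525 in the 4 libraries of these fetuses and at most 32 in the other 4. The mean level in the low libraries was 0.157% to 0.264% of that in the high ones across the 5 genes. Of 7 genes picked on the gyrus libraries alone, 5 showed the same fetuses in sulcus, and of 5 picked on the sulcus libraries 5 did so in gyrus. The tables argue against an exchange of single libraries between fetuses: over 13221 genes each library deviated from its region mean most like its own partner among the libraries of the other region, by a margin in the correlation of at least 0.113 (resampling interval over genes 0.0629 to 0.165). An exchange of both libraries of a fetus together stays open. A sex difference between the fetuses is a hypothesis that may account for the set; it was not tested, because the identifiers carry no chromosome.

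The gene with the largest gyrus to sulcus differences among the 7085 at 10 CPM or more was ENSOARG00000016718. Its log2 difference was 3.90 in ewe 1 fetus 1, -0.95 in ewe 1 fetus 2, -5.21 in ewe 2 fetus 1 and -3.03 in ewe 2 fetus 2. The gene had an unadjusted p of 0.49 in the main fit (edgeR quasi-likelihood test, adjusted p 0.99). It ranged from 188 CPM to 16519 CPM, up to 1.55% of a library's counts, and only 1 other gene at this abundance differed by over 3 on the log2 scale in any fetus (2 in all).

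Exchanges of region labels were also counted. Among the 8 arrangements that part all 4 fetuses, 4 gave at least the real 512 genes at an unadjusted p below 0.05, and the highest other gave 880; 8 arrangements are too few for a share under 0.05. Without the block, 29 of the 35 splits of the libraries into 4 and 4 gave at least the real 205 genes. Of these 35, 27 do not part all 4 fetuses and so also count differences between fetuses. Among the 8 that do, 3 gave at least 205 and the highest other gave 263, and 8 are too few for a share under 0.05. The highest of the 35, 2600, was the split of ewe 1 from ewe 2, which called 569 genes. The other 2 splits that kept both libraries of each fetus together called 7 and 0 genes. Libraries of different fetuses correlated at 0.952 to 0.958 in ewe 1 and at 0.948 to 0.962 in ewe 2. Between ewes they correlated at 0.930 to 0.966, so the ranges overlap. The fits of these splits count the 2 libraries of a fetus as separate replicates, so the counts of 2600 and 569 are too high. With counts summed per fetus, 2 fetuses against 2, 19 of 14729 genes differed between the ewes (edgeR quasi-likelihood test, lowest adjusted p 0.0438), 2 higher and 17 lower in ewe 2. A litter effect and a shared processing day cannot be told apart with these labels.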
